A study of Rattus norvegicus with 12 samples.

How the data were processed

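Kidney RNA was measured on 12 single-colour oligonucleotide arrays, CodeLink whole genome arrays for the rat, 1 array per sample. The labels place 4 arrays in each of 3 groups of male Fischer 344 rats: young rats of 4 months fed freely, rats of 24 months fed freely (ad libitum), and rats of 24 months under caloric restriction. Per the labels, restriction began at 10 weeks of age with 10% less food, went to 25% at 15 weeks and to 40% from 4 months on. Kidneys were taken under anaesthesia and snap frozen, total RNA was extracted, and biotin-labelled cRNA was hybridised, per the labels' protocols. The labels call the 4 samples of a group biological replicates and give them the numbers 1 to 4.

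The deposited array reports hold, for every spot, an intensity on a linear scale from which the local background had already been subtracted, so that values below 0 occur, together with a quality flag. Per the file headers the reports were written by CodeLink Expression Analysis version 4.1.0.29054, which also gave a second intensity scaled by the array median with a trim of 20%. The deposited value table of the series holds a ratio: each value is the report's median-scaled intensity divided by a constant for the probe. That ratio was the same on all arrays, within a relative tolerance of 0.01, for 33750 of the 33848 probes that could be compared (99.7%), and the probe's median over the arrays was 1 within the same tolerance for 89.8% of probes. The lowest value of that table was 0.01, and the medians of its 12 columns lay between 0.942 and 1.21. Its centring on the probe median was found from the values, and the statistic used by the authors is not given in the sources used here. Why the other probes have another median is not known.

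The background-subtracted intensity was the starting point. Control spots were left out, values with a contaminated, irregular or masked flag were treated as missing, and saturated spots were kept. The 33849 gene probes were quantile normalised between arrays, a floor of 7.7 was set (2.94 on the log2 scale, the median signal of the 256 negative control spots carried to the normalised scale), and log2 was taken. A probe was tested when it was above background on at least 4 of the 12 arrays and had at least 2 values in each group, which left 25398 probes (75%). The depth of an array is its signal over background, given for each group in the report, and the number of arrays limits the precision.

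Probe names came from the platform annotation for 16878 probes, from a match of the RefSeq accession for 183 and from the description for 21. In all 17082 probes had 1 gene symbol, 182 had several and 16585 had none. Genes were named only from probes with 1 symbol, which gave 12722 symbols, 11025 of them tested. For a gene list each gene was represented by the tested probe with the highest mean. Of 2566 genes with several tested probes, calls in both directions occurred in 168 genes between the aged ad libitum and young groups, in 5 between the diets and in 110 between the restricted and young groups. Where another probe of a named gene differed in its call, its value is given.

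Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 12 arrays in 1 fit, a mean per group and no covariate. Adjusted p-values are Benjamini-Hochberg values over all probes tested, with a threshold of 0.05. The comparisons were aged ad libitum against young, aged restricted against aged ad libitum, and aged restricted against young. Probes that passed in the first and second with opposite signs were counted beside the count for independent lists, and the covariance of the changes was set beside that in simulated unchanged groups that share the ad libitum arrays. The lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 31 lists and 3 comparisons together. The lists covered complement, B and plasma cells, T and natural killer cells, macrophages and myeloid cells, MHC and antigen presentation, chemokines and cytokines, interferon response, extracellular matrix and fibrosis, tubular injury markers, claudins and tight junctions, proximal tubule, loop of Henle and distal tubule, collecting duct, glomerulus and podocytes, endothelium, adrenal gland, adipocytes, red blood cells, skeletal muscle and urothelium. They also covered oxidative stress and glutathione, heat shock and chaperones, oxidative phosphorylation, fatty acid oxidation and ketogenesis, cholesterol and fatty acid synthesis, the circadian clock, cell cycle and proliferation, senescence and apoptosis, insulin, IGF and Klotho signalling, and renin-angiotensin and vasoactive genes. A last list held Havcr1, Cldn7 and Mmp7, the genes the study is known to have named.

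The groups, the tests, the lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. The rule took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among probes with a symbol, an adjusted p under 0.05 and no overlap between the arrays of the groups. Numbered loci were skipped. It also took the 10 genes with the largest smaller change among the opposed ones, up to 4 members of each list with the lowest p, and the study's named genes. Some of the genes so named are not reported here. A probe near background on every array of a group has only a bound there. Its difference is given as at least N-fold, the mean of the brighter group against a mean in the dimmer group of, per array, the higher of the lowest signal called above background and the probe's own value.

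Arrays of a group were compared before they were averaged. Each spread is an SD scaled from the median absolute log2 difference, which larger differences at a minority of probes do not move. The spread between arrays was set against the spread between repeat spots of the same control probe on 1 array, among spots brighter than 2 times the array median, with the 97.5th percentile of 2000 bootstrap draws as the upper limit. Arrays whose difference stayed within that limit were joined, directly or through another array, and counted as 1 sample, which gave 5 samples. Standard errors printed beside a log2 change come from the fit over these 5 samples, where n = 5 counts the samples in the fit and the lone ad libitum sample is assumed to vary like those of the other groups, while calls and adjusted p-values come from the fit over 12 arrays. The p-values over arrays therefore measure the spread between arrays, which may be technical. The standard errors are limma's moderated ones, drawn partly from a spread common to all probes.

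Simulated data held 25398 probes, with 50 changed at each of 4 fold sizes and none of these among the dimmest. Simulated arrays varied independently, so shares over 12 arrays do not carry over to arrays joined into 1 sample. The procedure was tested on these data. Over 12 arrays it recovered 52% of 1.5-fold, 86% of 2-fold and 98% of 4-fold changes between aged ad libitum and young, 54%, 84% and 98% between the diets, and 52%, 86% and 98% between restricted and young. For 1.25-fold changes the shares were 4%, 4% and 6%. Over 5 samples it recovered 0% at each size in both comparisons with the ad libitum group, and 4% of 2-fold and 92% of 4-fold changes between restricted and young.

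The other settings fixed then were an added 50 before normalisation, array median scaling, cyclic loess, the value table, no filter or a stricter filter on dim probes, no floor, kept quality flags, a fit of only the 2 groups compared, a variance trend with a robust fit, array weights, the replicate number as a block, the slide series as a block, each array left out in turn, a minimum change of 1.5-fold, the mean over a gene's probes and the estimated correlation. Added after seeing the data were the 5-sample fit, fits without young arrays 1 and 2 or without young arrays 3 and 4, and comparisons within each slide series. Slide series 1 held the 4 ad libitum arrays and restricted arrays 3 and 4, and slide series 2 held the young arrays and restricted arrays 1 and 2. The ad libitum arrays were scanned apart from all others, so for both comparisons with that group the scan and the group cannot be told apart.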

Results

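Gene expression was measured in whole kidney of male Fischer 344 rats, an inbred strain often used in studies of ageing, on 12 arrays in 3 groups of 4: young freely fed rats of 4 months, freely fed rats of 24 months (ad libitum) and rats of 24 months kept on 40% restriction of food. Between 64.2% and 69.9% of gene probes lay above background on the young arrays, against 71.5% to 73.7% on the ad libitum arrays and 72.5% to 74.8% on the restricted arrays. The median background-subtracted intensity ran from 74.5 to 117 in the young group, from 113.6 to 130 in the ad libitum group and from 129.7 to 158.6 in the restricted group. In two-sided exact permutation tests of these measures between groups, unadjusted p lay between 0.0286, the smallest value that 4 arrays against 4 allow, and 0.0571, and the adjusted p was 0.0571 in each of the 6 tests. Between 32 and 59 spots per array were saturated.

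Several arrays of a group differed by no more than the upper limit for repeat spots on an array. Over 9026 bright probes, the ad libitum arrays differed by SDs of 0.063 to 0.0896 on the log2 scale. These SDs are scaled from the median absolute difference, which larger differences at a minority of probes do not move. All ad libitum pairs stayed within the limit but 1 and 4 (0.0873, limit 0.0834), which were joined through the others. Restricted arrays 1 and 3, restricted arrays 2 and 4, young arrays 1 and 2 and young arrays 3 and 4 also stayed within it. Arrays joined in this way were counted as 1 sample, so that the ad libitum group held 1 sample and each other group 2, which makes n = 5 in all. Young arrays of different samples differed by SDs of 0.241 to 0.273, restricted and ad libitum arrays by 0.152 to 0.197, and ad libitum and young arrays by 0.253 to 0.381. Standard errors below come from a fit over these 5 samples. The comparisons with the ad libitum group set 1 sample against 2. The lone ad libitum sample is assumed to vary like those of the young and restricted groups, which supply all of the spread between samples. Standard errors are moderated by limma, so each draws partly on a spread common to all probes (2.69 prior degrees of freedom). Calls are those of the 12-array fit, whose p-values measure only the spread between arrays.

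**Figure D1:**
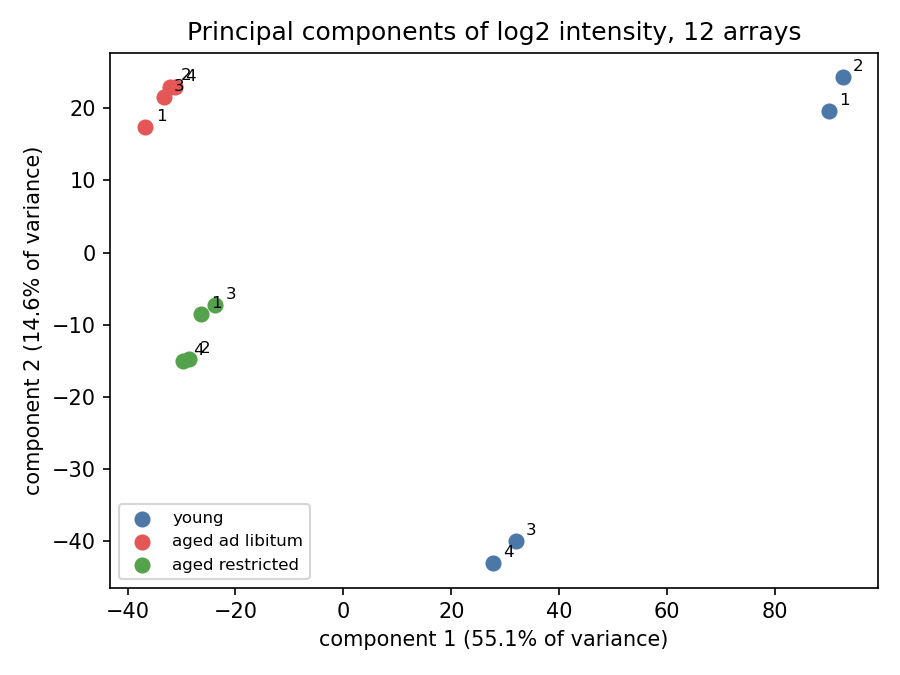
Principal components 1 (55.1% of the variance) and 2 (14.6%) of normalised log2 intensity, 1 point per array, coloured by group and marked with the replicate number. The 4 young arrays fall into pairs 1 and 2 and 3 and 4, which differ by SDs of 0.241 to 0.273 on bright probes.

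The first comparison asked what differed between 24 and 4 months under free feeding. The aged kidneys had higher levels of Pnoc, the precursor of the neuropeptide nociceptin, by 5.54 on the log2 scale (SE 0.31, n = 5 samples). Its limma adjusted p was 1.08e-09. That p, like the others for single genes, comes from the fit over all arrays and does not rest on n = 5. Spp1, which encodes osteopontin, was higher by 4.94 (SE 0.89). The secreted lectin Reg3b rose by 4.33 (SE 0.31), the cytokine Il24 by 4.07 (SE 0.19) and Car3, a carbonic anhydrase abundant in muscle and fat and above background on 1 of 4 young arrays, by 3.85 (SE 0.51). The organic anion transporter Slco1a1 fell by 8.69 (SE 0.23, adjusted p = 4.16e-09), with a value above background on only 1 of 4 ad libitum arrays. On these 4 arrays its log2 values ran from 3.28 to 4.98, a spread that the SE leaves out. Its other probe was near background on all 4 of them. Immune cell markers, matrix genes and tubular injury markers rose as groups.

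Among the other genes with the largest rises were Havcr1, the kidney injury molecule, at 3.81 (SE 0.31) with a further probe at 2.42, Dcaf12l1 at 3.38 (SE 0.71) with a further probe at 2.42, and lysozyme 2 (Lyz2) at 3.32 (SE 0.55). The fibrillar collagen gene Col24a1 rose by 3.46 (SE 0.33), but its second probe was at -0.38 and did not pass. The class I MHC gene RT1-CE12, from a family whose probes can cross-hybridise, rose by 3.40 (SE 0.52), with a second probe at 0.41 that did not pass. Gc, the vitamin D binding protein, fell by 3.75 (SE 0.21) and the annexin Anxa13 fell by 3.17 (SE 0.20). Gucy1b2, a guanylate cyclase subunit, fell by 3.15 (SE 0.23), Bfsp2 fell by 3.24 (SE 0.45), Tm4sf20 fell by 2.91 (SE 0.30) and Eps8l3 fell by 2.89 (SE 0.69). Slc35f1 fell by 3.18 (SE 0.21) and was above background on 1 of 4 ad libitum arrays. The steroid dehydrogenase Hsd3b2 was at least 13.1-fold lower in the aged kidneys, where it was not above background, with a second probe at -0.79. Cyp2c11, a cytochrome P450 of male rats, whose family can also cross-hybridise, was at least 8.57-fold lower (adjusted p = 0.000352).

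Markers of leukocytes were higher in aged kidney. List p-values here and below use the preset correlation unless another is named, and lists that passed had a higher adjusted p with the estimated one. With age that gave 0.000373 for macrophages, 0.000621 for T and natural killer cells, 0.0158 for B and plasma cells and 0.00222 for MHC. Other splits of the 12 arrays had a median of 23 list tests past the threshold, so small list p-values overstate the certainty. Of 30 macrophage and myeloid genes 25 rose, 0 fell and 5 did not pass (26 and 1 adjusted over the list alone; camera adjusted p = 7.07e-14). Among them were the leukocyte phosphatase Ptprc at 2.19 (SE 0.22) and the calcium-binding S100a9 at 2.16 (SE 0.19). Of 21 T and natural killer cell genes 19 rose and 2 did not pass, the same counts as adjusted over the list alone (adjusted p = 9.93e-11). The kinase Lck rose by 2.60 (SE 0.24) and perforin (Prf1) by 2.22 (SE 0.23). The B and plasma cell list had 6 of 8 genes higher, also when adjusted over the list alone (adjusted p = 6.02e-05). The B cell receptor chain Cd79b rose by 2.64 (SE 0.20) and the immunoglobulin joining chain (Jchain) by 2.87 (SE 0.24). Complement had 13 of 20 genes higher and none lower, likewise adjusted over the list alone (adjusted p = 2.09e-06). C1qb rose by 2.27 (SE 0.22) and C3 by 1.76 (SE 0.26). In MHC and antigen presentation 17 of 18 genes rose and 1 fell, also adjusted over the list alone (adjusted p = 8.32e-08). The peptide transporter Tap2 stood at 1.31 (SE 0.21) and RT1-Da at 2.06 (SE 0.40). Chemokines and cytokines had 22 genes higher, 6 lower and 12 that did not pass (23 and 6 adjusted over the list alone; adjusted p = 4.51e-05). The lymphoid chemokine Ccl21 rose by 3.13 (SE 0.25) and the T cell chemokine Ccl5 by 2.81 (SE 0.25). The interferon list had 13 of 24 higher and 1 lower, also adjusted over the list alone, with an adjusted p of 0.018, but adjusted p = 0.129 with an estimated correlation and 0.144 without young arrays 3 and 4. Irf1 rose by 1.03 (SE 0.26) and Bst2 by 1.16 (SE 0.21).

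The matrix and fibrosis list had 37 of 56 genes higher, 6 lower and 13 that did not pass (39 and 7 adjusted over the list alone; adjusted p = 1.87e-08). Tenascin C (Tnc) rose by 1.98 (SE 0.19) and fibronectin (Fn1) by 1.57 (SE 0.19). Of 30 tubular injury markers 24 rose and 3 fell, also adjusted over the list alone (adjusted p = 5.17e-07). Clusterin (Clu) rose by 2.34 (SE 0.20) and ceruloplasmin (Cp) by 2.73 (SE 0.29), while the trefoil factor Tff3 fell by 2.37 (SE 0.20). The senescence and apoptosis list had 21 of 35 genes higher and 4 lower (21 and 5 adjusted over the list alone; adjusted p = 0.000358). Casp12, a caspase of the endoplasmic reticulum, rose by 1.46 (SE 0.21) and Apaf1, which nucleates the apoptosome, by 1.07 (SE 0.19). All 3 genes the study is known to have named rose, also adjusted over the list alone (adjusted p = 0.000246): Havcr1, the tight junction protein Cldn7 at 3.08 (SE 0.26) and the matrix metalloproteinase Mmp7 at 3.02 (SE 0.21). That list was chosen on these samples and is not independent evidence of its direction.

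Among kidney cell markers, 11 of 27 genes of the loop of Henle and distal tubule fell and 1 rose, also adjusted over the list alone. The potassium channel Kcnj1 stood at -1.24 (SE 0.27) and the chloride channel subunit Bsnd at -0.90 (SE 0.21). The list's adjusted p was 0.023, but adjusted p = 0.132 with an estimated correlation and 0.447 without young arrays 3 and 4. The endothelium list had 11 of 28 higher and 2 lower, also adjusted over the list alone, including the lymphatic marker Lyve1 at 1.21 (SE 0.29). Its adjusted p was 0.0391, but adjusted p = 0.149 with an estimated correlation, 0.117 under array median scaling, 0.0609 over 5 samples and 0.113 without young arrays 1 and 2. The remaining lists did not pass. The proximal tubule list had 8 of 43 genes higher and 14 lower (9 and 15 adjusted over the list alone; adjusted p = 0.324). Collecting duct had 2 of 28 higher and 10 lower (adjusted p = 0.0994), and glomerulus and podocytes 8 of 25 higher and 2 lower (adjusted p = 0.22), both with the same counts adjusted over the list alone. Claudins and tight junctions had 6 of 17 higher and 2 lower (adjusted p = 0.325) and oxidative stress and glutathione 13 of 39 higher and 11 lower (adjusted p = 0.822), both with the same counts adjusted over the list alone. For heat shock and chaperones 7 of 28 were higher and 9 lower (7 and 10 adjusted over the list alone; adjusted p = 0.614). For oxidative phosphorylation 4 of 57 were higher and 14 lower (4 and 13 adjusted over the list alone; adjusted p = 0.337). Under array median scaling 4 lists passed that did not in the planned fit. Oxidative phosphorylation (adjusted p = 2.59e-05) and proximal tubule (0.0275) were then lower, and skeletal muscle (0.0222) and cell cycle genes (0.0386) higher. Fatty acid oxidation and ketogenesis had 14 of 47 higher and 9 lower (adjusted p = 0.559), cholesterol and fatty acid synthesis 3 of 35 higher and 14 lower (adjusted p = 0.057) and the circadian clock 7 of 18 higher and 7 lower (adjusted p = 0.832), all with the same counts adjusted over the list alone. Cell cycle and proliferation had 15 of 43 higher and 8 lower (16 and 8 adjusted over the list alone; adjusted p = 0.257), and insulin, IGF and Klotho signalling 9 of 34 higher and 8 lower (9 and 10 adjusted over the list alone; adjusted p = 0.798). Of 23 renin-angiotensin and vasoactive genes 6 were higher and 7 lower (7 and 7 adjusted over the list alone; adjusted p = 0.932). Among tissues a dissection could carry along, adipocyte genes had 6 of 13 higher and 3 lower (6 and 4 adjusted over the list alone; adjusted p = 0.384) and skeletal muscle 5 of 12 higher and 2 lower (6 and 2 over the list alone; adjusted p = 0.207). Adrenal gland had 1 of 9 higher and 2 lower (0 and 2 over the list alone; adjusted p = 0.589), red blood cells 1 of 5 higher and 2 lower (2 and 3 over the list alone; adjusted p = 0.441) and urothelium 0 of 5 higher and 1 lower (0 and 0 over the list alone; adjusted p = 0.584). Median and mean differed in sign for the heat shock, circadian and insulin lists, whose tests pointed down, and for the renin-angiotensin list, whose test pointed up.

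In total 12204 of 25398 probes (48.1%) passed, 5318 higher and 6886 lower in aged ad libitum kidney, 1672 and 885 of them by at least 2-fold, which covered 6067 named genes. Under array median scaling 29.6% of the calls were higher in place of 43.6%. That scaling moved the median of all probes from -0.05 to -0.21, so single directions hold relative to the median probe. Over 5 samples, with the lone ad libitum sample lending no spread of its own, far fewer probes passed. In fits over arrays, not samples, 8308 probes were called the same way against each pair of young arrays. Those fits counted arrays of the same sample separately, so 8308 is not a count at the level of samples. With the slide series as a block 3887 probes passed and the interferon (adjusted p = 0.0507) and endothelium (adjusted p = 0.0907) lists no longer did. That block was estimated from the restricted arrays alone, the only group in both series, so lost precision may lower the count. No slide series held both groups and all ad libitum arrays were scanned apart, so for a single probe scan and age cannot be told apart. Restricted and young arrays shared a scan, which does not account for differences between those groups.

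The second comparison asked how restriction changed the kidney at 24 months. Restricted rats had lower levels of Cldn7, a tight junction claudin, which fell by 2.74 (SE 0.26, n = 5 samples). Its limma adjusted p was 8.78e-07 in the fit over all arrays, which counts arrays of the same sample separately. The pantetheinase Vnn1 fell by 2.42 (SE 0.25, adjusted p = 7.75e-07). Fkbp5, a co-chaperone of the glucocorticoid receptor, fell by 2.31 (SE 0.26), with its second probe at -2.05. The aldo-keto reductase Akr1b7 rose by 2.96 (SE 0.44, adjusted p = 1.67e-05) and Slco1a1 by 2.58 (SE 0.23), from ad libitum arrays of which 1 of 4 was above background and with the second probe near background on all 4. Fatty acid oxidation and ketogenesis genes fell as a group, while cell cycle, interferon and matrix genes rose.

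Of the other large falls, the mitochondrial carrier Slc25a25 fell by 2.37 (SE 0.41) and serine dehydratase (Sds) fell by 2.21 (SE 0.34) with a second probe at -1.71. The transcription factor Onecut2 fell by 2.08 (SE 0.64) with 1 of 4 restricted arrays above background. Vstm4 fell by 2.07 (SE 0.21), with a second probe at -0.08 that did not pass. Camsap2, a microtubule end-binding protein, was at least 4.86-fold lower with restriction (second probe -0.09, not passed) and Lyzl4 at least 4.07-fold lower (adjusted p = 2.92e-05). Several of the rises rested on 1 probe of a gene. The RNA helicase Ddx6 rose by 1.96 (SE 0.28, second probe 0.15), the export pump Abcc2 by 1.51 (SE 0.23, second probe -0.03). The caveolar protein Cavin1 rose by 1.51 (SE 0.30, second probe 0.00) and Hs1bp3 by 1.5 (SE 0.19, other probes -0.22 and 0.12). None of these further probes passed. Cavin1 was above background on 1 of 4 ad libitum arrays and lost its call under array median scaling (1.42, adjusted p = 0.0523). The ghrelin gene Ghrl rose by 1.22 (SE 0.28), with 3 of 4 ad libitum arrays above background and a second probe at -0.01. Pimreg, a mitotic regulator above background on 1 of 4 ad libitum arrays, rose by 1.89 (SE 0.29), and Borcs8, a subunit of a lysosome-positioning complex, by 1.46 (SE 0.30). One probe of the orphan nuclear receptor Nr4a3 was at least 2.73-fold higher, whereas another fell by 1.16 and the last stood at -0.36 and did not pass.

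In fatty acid oxidation and ketogenesis 18 of 47 genes fell, 2 rose and 27 did not pass (21 and 3 adjusted over the list alone; camera adjusted p = 5.28e-07). The peroxisomal enzyme Ehhadh fell by 1.02 (SE 0.25) and the fatty acid hydroxylase Cyp4a8 by 0.75 (SE 0.19), with other Cyp4a8 probes at -0.21 and 0.17 that did not pass. Bdh1, a ketone body dehydrogenase, rose by 0.77 (SE 0.19). Of 13 adipocyte markers 4 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.0078, but adjusted p = 0.0993 with an estimated correlation and 0.0747 under array median scaling). The fatty acid binding protein Fabp4 stood at -0.97 (SE 0.20) and the triglyceride lipase Pnpla2 at -0.62 (SE 0.22). Of 43 proximal tubule genes 8 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.0113, but adjusted p = 0.281 with an estimated correlation). The gluconeogenic enzymes Pck1 and G6pc1 fell by 1.09 (SE 0.25) and by 0.96 (SE 0.26). The circadian list had 4 of 18 lower and 1 higher (6 and 2 adjusted over the list alone; adjusted p = 0.0323, but adjusted p = 0.0756 with an estimated correlation). Its members Per1, a clock repressor, and Usp2, a rhythmic deubiquitinase, fell by 1.77 (SE 0.20) and by 1.10 (SE 0.24). Dbp, a clock output factor, rose by 0.36 (SE 0.22, adjusted p = 0.0377), which did not pass under array median scaling (0.20, adjusted p = 0.282). That list was also lost under array median scaling (adjusted p = 0.0565), within slide series 1 (adjusted p = 0.0857), and without young arrays 1 and 2 (0.0628) or 3 and 4 (0.0739). The hour at which kidneys were taken is not given in the sources used here.

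Cell cycle and proliferation genes rose, 18 of 43 with 0 lower (23 and 1 adjusted over the list alone; adjusted p = 7.09e-10). The mitotic ubiquitin-conjugating enzyme Ube2c rose by 1.20 (SE 0.21), the kinesin Kif20a by 0.85 (SE 0.20) and cyclin A2 (Ccna2) by 0.73 (SE 0.20). In the interferon list 9 of 24 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 1.28e-05). The antiviral protein Rsad2 rose by 0.75 (SE 0.20) and Usp18 by 0.91 (SE 0.36), whose second probe stood at 0.19 and did not pass. Matrix genes had 14 of 56 higher and 2 lower (21 and 4 adjusted over the list alone; adjusted p = 2.09e-06). Fibrillin 1 (Fbn1) rose by 0.90 (SE 0.25) and the basement membrane collagen Col4a1 by 0.45 (SE 0.19; 0.25 and not passed under array median scaling). In MHC and antigen presentation 2 of 18 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0225, but adjusted p = 0.0812 with an estimated correlation and 0.186 under array median scaling). The proteasome subunit Psmb9 stood at 0.36 (SE 0.20; 0.21 and not passed under that scaling). The loop of Henle and distal tubule list had 7 of 27 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00228, but adjusted p = 0.0592 with an estimated correlation and 0.0644 under array median scaling). Uromodulin (Umod) and the sodium chloride cotransporter Slc12a3 both stood at 0.51 (SE 0.21 and 0.24), neither of which passed under array median scaling (0.24 and 0.23). T and natural killer cell genes had 4 of 21 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.0279, but adjusted p = 0.0661 with an estimated correlation, 0.0802 under array median scaling and 0.0506 with the slide series as a block). Gzmk, a granule protease above background on 1 of 4 restricted arrays, stood at -1.38 (SE 0.31) and Nkg7 at -0.85 (SE 0.24). All 3 genes the study is known to have named fell, also adjusted over the list alone (adjusted p = 6.18e-06), again a list that is not independent evidence of its direction. Mmp7 stood at -1.46 (SE 0.21) and Havcr1 at -0.94 (SE 0.31, second probe -0.80, not passed). The other 20 lists gave adjusted p between 0.115 and 0.966, of which complement passed as lower within slide series 1 (0.0409). Median and mean or test differed in sign for the oxidative phosphorylation, cholesterol and senescence lists.

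**Figure D2:**
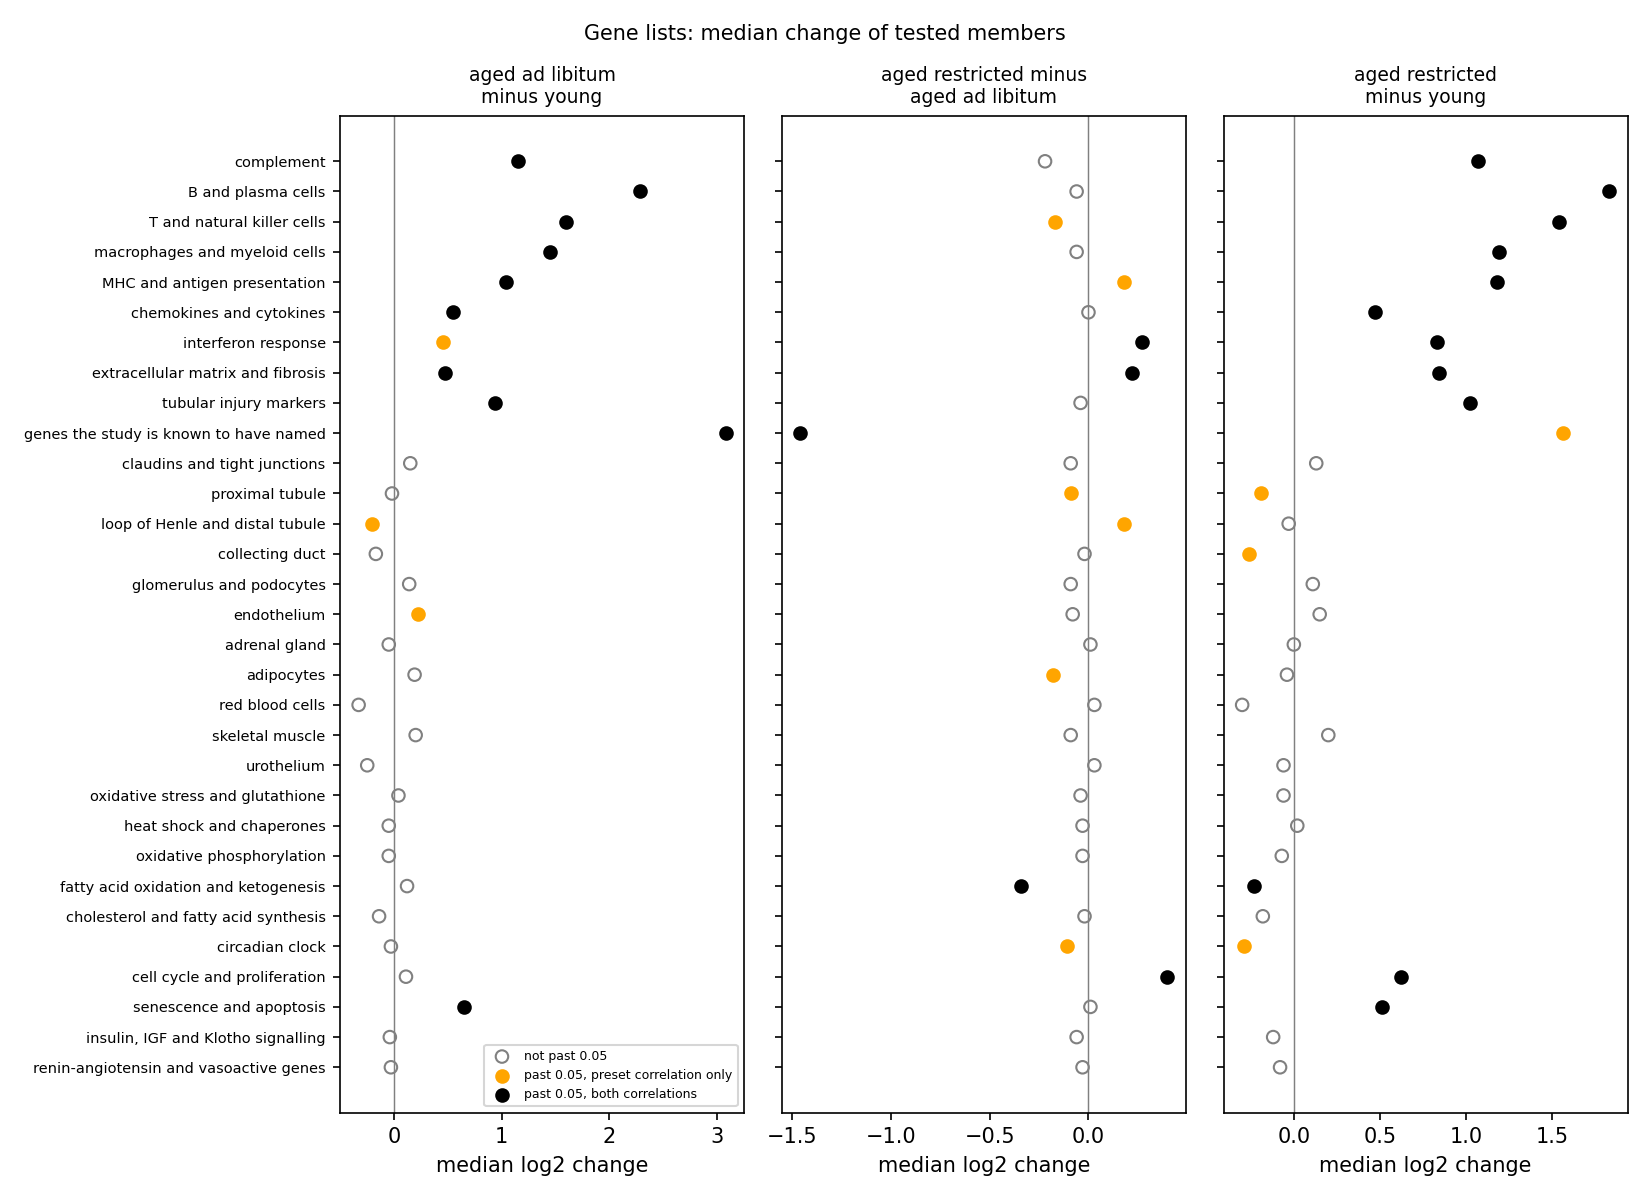
Median log2 change of the tested members of each of the 31 gene lists in the 3 comparisons, with members near background in a whole group at their bound. Black points passed 0.05 with the preset and the estimated correlation, orange points with the preset one only, and open points did not pass; macrophage genes stood at 1.45 with age, and cell cycle genes at 0.40 with restriction.

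Between the diets 3397 probes (13.4%) passed, 1878 higher and 1519 lower with restriction, 203 and 218 of them by at least 2-fold, which covered 1560 named genes. Array median scaling turned the share of higher calls from 55.3% to 44.3%. Over 5 samples, where the ad libitum group held only 1, no diet difference was shown. Low unadjusted limma p-values were no more frequent there than expected with no change. The simulation does not account for this, since it changed far fewer probes than were called here. With the slide series as a block 1479 probes passed, and within slide series 1, the one that held both diets, 4147 did (2051 higher, 2096 lower). Of these 4147, 2499 were shared with the planned fit. The fit within that series left out the young arrays and their spread, so 4147 is not to be set against 3397. A fit of only the 2 diet groups over both series gave 7302. The ad libitum arrays were scanned apart from the restricted ones, so diet and scan cannot be told apart.

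The third question was which age differences restriction opposed. Cldn7 rose by 3.08 with age and fell by 2.74 with restriction, ending at 0.33 (SE 0.22, adjusted p = 0.0613) between restricted and young rats. That last difference passed under array median scaling (0.35, adjusted p = 0.0471). Fkbp5 went from 2.49 (SE 0.26) with age to -2.31, Sds from 2.19 (SE 0.34) to -2.21 and Vstm4 from 2.08 (SE 0.21) to -2.07. A second probe of Vstm4 fell by 0.28 with age. The pancreatic-type lipase Pnliprp2 rose by 2.86 (SE 0.26) with age and fell by 1.78 (SE 0.26) with restriction, and Angptl4, an inhibitor of lipoprotein lipase, rose by 2.11 (SE 0.63) and fell by 1.52 (SE 0.63). Slco1a1, Ddx6 and Hs1bp3 went the other way, with age changes of -8.69, -2.59 (SE 0.28; second probe -0.02, not passed) and -1.62 (SE 0.19) and rises of 2.58, 1.96 and 1.5 with restriction. Both values of Slco1a1 are set against ad libitum arrays of which 1 of 4 was above background, and its second probe was near background on all 4. The water channel Aqp1 rose by 1.49 (SE 0.85, adjusted p = 0.0199) and fell by 1.62 (SE 0.85), but its age call did not hold against both pairs of young arrays.

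**Figure D3:**
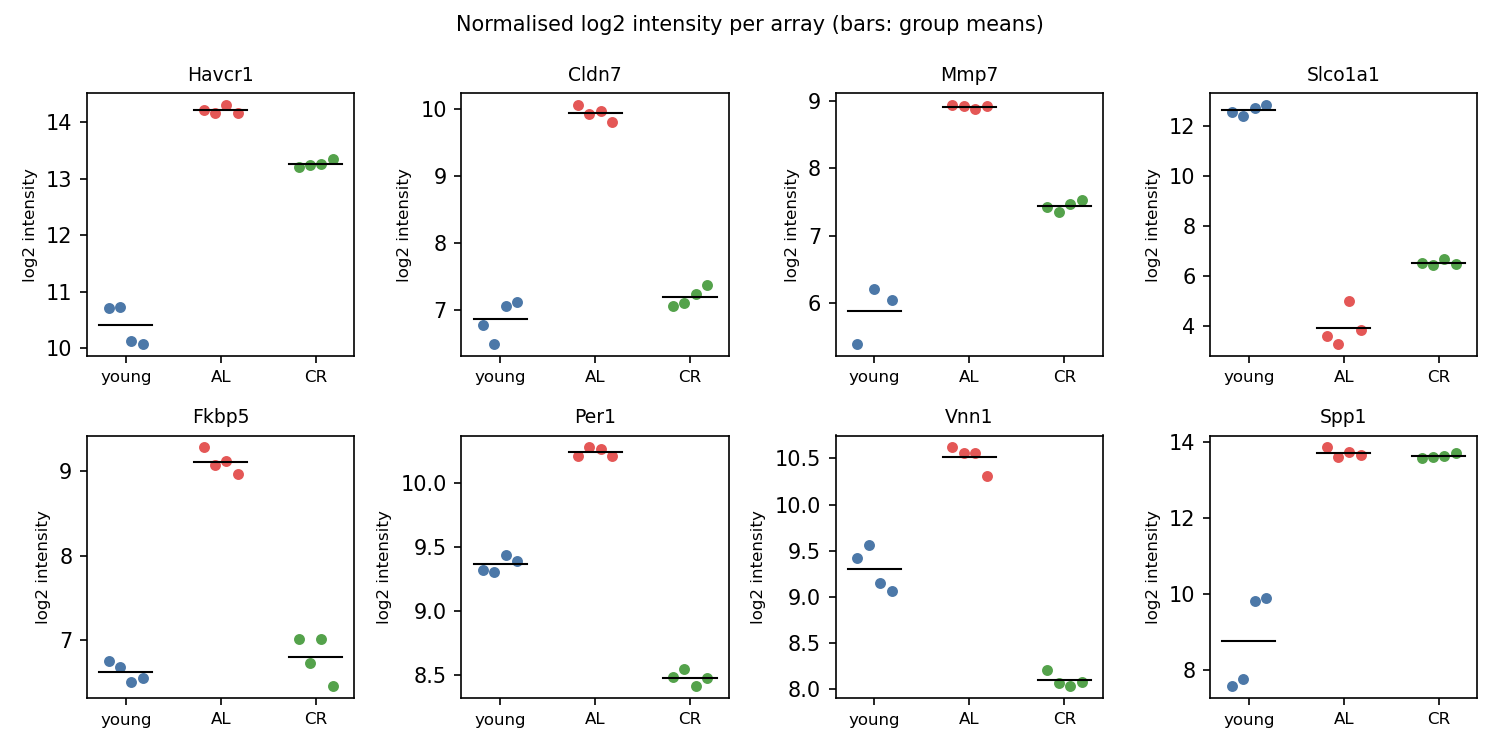
Normalised log2 intensity of Havcr1, Cldn7, Mmp7, Slco1a1, Fkbp5, Per1, Vnn1 and Spp1 on each array, with a bar at each group mean, for young, aged ad libitum (AL) and aged restricted (CR) rats; Mmp7 has 3 young values. Cldn7 differed by 3.08 between aged ad libitum and young and by -2.74 between the diets, and young Spp1 values lie apart in pairs.

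In all 1836 probes changed with age and the opposite way with restriction, 809 higher with age and 1027 lower, and they included 814 named genes. The ad libitum arrays, scanned apart from all others, enter both comparisons with opposite signs, so scan and opposition cannot be told apart. They made up 54% of the probes changed by diet and 15% of those changed by age, and 396 probes moved the same way in both. Independent lists of the same sizes, which do not share the ad libitum arrays as these do, would share 318 and 509 probes in these directions. Of the 1836, 1130 did not pass between restricted and young rats, 531 still differed in the direction of age and 175 against it. Across probes, which are not independent, the covariance of age and diet changes was -0.0913 against -0.0191 in simulated unchanged groups, a difference of -0.0722. The r was -0.374 against -0.5, and 60.8% of probes had opposite signs against 66.7%. The simulated r of -0.5 belongs to groups of equally many independent arrays, whereas the joined samples were not equally many per group. The simulation therefore gives no baseline for joined samples, and no conclusion is drawn from the difference. With the ad libitum arrays split between the comparisons the covariance lay between -0.0844 and -0.0739, r between -0.338 and -0.284 and the opposite calls between 720 and 809 over 6 splits. All but 1 pair of the ad libitum arrays stayed within the limit for repeat spots, so such a split may not part separate samples. Part or all of the opposition may then come from the shared sample. Over 5 samples limma gave 0 opposite calls, and 594 probes were opposite with the slide series as a block.

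The last comparison set restricted rats of 24 months against young rats. Pnoc was higher by 5.14 (SE 0.25, n = 5 samples), Spp1 by 4.86 (SE 0.72), Reg3b by 4.44 (SE 0.25) and Car3 by 4.07 (SE 0.42). The limma adjusted p of Pnoc was 3.32e-09 in the fit over all arrays. Slco1a1 fell by 6.11 (SE 0.19) and Gc fell by 3.92 (SE 0.17). The protease inhibitor A2m rose by 4.40 (SE 0.78), with 2 of 4 young arrays above background, and Akr1b7 rose by 3.97 (SE 0.36), with 3 of 4. Cthrc1, a secreted matrix-associated protein above background on 1 of 4 young arrays, rose by 3.52 (SE 0.20). Immune, interferon, matrix and cell cycle lists rose.

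Col24a1 rose by 4.04 (SE 0.27; second probe 0.25, not passed), Dcaf12l1 by 3.65 (SE 0.58) and RT1-CE12 by 3.46 (SE 0.43). Eps8l3 fell by 3.44 (SE 0.56), Anxa13 fell by 3.25 (SE 0.17) and Bfsp2 fell by 3.16 (SE 0.37). Gucy1b2 fell by 2.85 (SE 0.19) and Tm4sf20 fell by 2.84 (SE 0.24). In restricted rats Hsd3b2 was at least 14-fold lower than in young rats (second probe -0.76), Cyp2c11 at least 11.1-fold lower and Tcp11x2 at least 6.67-fold lower (adjusted p = 1.01e-06). Of the genes the study is known to have named, Havcr1 at 2.87 (SE 0.25) and Mmp7 at 1.56 (SE 0.17) passed and Cldn7 did not. Adjusted over the list alone 3 passed, which is not independent evidence (adjusted p = 0.0122, but adjusted p = 0.0591 with an estimated correlation).

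The interferon list had 22 of 24 genes higher and 0 lower, also adjusted over the list alone (camera adjusted p = 5.75e-07). The antiviral Mx1 rose by 1.24 (SE 0.26) and Ifi27 by 0.79 (SE 0.18), though Ifi27 did not pass under array median scaling (0.08). The matrix list had 41 of 56 higher and 2 lower (44 and 2 adjusted over the list alone; adjusted p = 1.72e-13), with Tnc at 2.40 (SE 0.16) and Fn1 at 1.89 (SE 0.16). In macrophages and myeloid cells 27 of 30 rose and 1 fell, in T and natural killer cells 17 of 21 and 1, and in MHC and antigen presentation 17 of 18 and 1. In complement 14 of 20 rose and 0 fell, in B and plasma cells 6 of 8 and 0, and in chemokines and cytokines 21 of 40 and 3. These 6 lists had the same counts adjusted over the list alone, with adjusted p of 7.07e-14, 1.36e-09, 1.97e-09, 9.63e-07, 0.000137 and 6.43e-06 in that order. Injury markers had 19 of 30 higher and 3 lower (20 and 3 adjusted over the list alone; adjusted p = 1.1e-05), with Clu at 2.30 (SE 0.16). Senescence and apoptosis had 20 of 35 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.000642), with the cyclin-dependent kinase inhibitor Cdkn2b at 2.07 (SE 0.25). Cell cycle genes had 25 of 43 higher and 2 lower (26 and 2 adjusted over the list alone; adjusted p = 5.17e-07), with Cks2 at 1.32 (SE 0.20) and topoisomerase Top2a at 1.12 (SE 0.22).

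Fatty acid oxidation and ketogenesis had 20 of 47 genes lower and 2 higher, also adjusted over the list alone (adjusted p = 0.0122, but adjusted p = 0.116 without young arrays 3 and 4). The thioesterase Acot12 stood at -1.92 (SE 0.32) and the coactivator Ppargc1a at -1.11 (SE 0.17). The proximal tubule list had 18 of 43 lower and 2 higher (adjusted p = 0.00864, but adjusted p = 0.271 with an estimated correlation and 0.447 without young arrays 3 and 4). The collecting duct list had 13 of 28 lower and 0 higher (adjusted p = 0.0258, but adjusted p = 0.251 with an estimated correlation and 0.447 without young arrays 3 and 4). Both had the same counts adjusted over the list alone. A member of the latter, the ammonia transporter Rhbg, fell by 0.55 (SE 0.16). The collecting duct list did not pass under array median scaling (adjusted p = 0.0774) or over 5 samples (0.0507). In the circadian list 10 of 18 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0447, but adjusted p = 0.0853 with an estimated correlation). Per1 stood at -0.88 (SE 0.16) and Usp2 at -0.81 (SE 0.20). That list was lost under array median scaling (0.134), with the slide series as a block (0.0507), within slide series 2 (0.0561), over 5 samples (0.0778) and without young arrays 3 and 4 (0.199). The other 15 lists gave adjusted p between 0.0513 and 0.966. Oxidative phosphorylation, at 0.337, passed as lower under array median scaling (1.41e-06). Median and mean differed in sign for the adipocyte, red blood cell, oxidative stress and heat shock lists, whose tests pointed down except for oxidative stress.

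Between restricted and young rats 11256 probes (44.3%) passed, 5015 higher and 6241 lower, 1543 and 709 of them by at least 2-fold, which covered 5666 named genes. The share of higher calls went from 44.6% to 25.2% under array median scaling, which moved the median of all probes to -0.24. Over 5 samples 231 probes passed (178 higher, 53 lower) and 7857 passed with the slide series as a block. Within slide series 2, the one that held both groups, 3417 passed (1450 higher, 1967 lower).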

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

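The tests of scan day, slide series, lower signal on young arrays, blood and tubule loss were chosen only after the results were seen, and the bounds for the blood and young-array tests were set again after their values were seen; the counts of other splits were planned before.

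In 15 of 314 groups of arrays (4.78%) an array lay apart from the other 3 by more than Dixon's critical value, and chance flags about 1 in 20 groups. Restricted array 4 had a median intensity of 130 against 155 to 159 on the others of its group, and young array 4 had 746 spots left out for quality against 139 to 167. The remaining cases are single genes on the log2 scale. Among the ad libitum arrays, Il24 was 9.69 on array 4 (others 9.82 to 9.83), Dcaf12l1 was 8.52 on array 1 (8.41 to 8.43), Hsd3b2 was 3.67 on array 2 (2.94, the floor, on the others), A2m was 7.89 on array 1 (8.01 to 8.03) and Cthrc1 was 7.37 on array 4 (7.51 to 7.53). Also there, Cd79b was 10.9 on array 4 (10.9 to 11), Ccl21 was 12.9 on array 1 (12.8), Pnpla2 was 12.8 on array 4 (12.8) and Apaf1 was 8.51 on array 4 (8.43 to 8.44). Among the restricted arrays, Abcc2 was 7.43 on array 1 (7.53 to 7.54) and Lyzl4 was 3.87 on array 2 (2.94, the floor). Among the young arrays, Clu was 10.2 on array 4 (10.1) and Apaf1 was 7.29 on array 2 (7.4 to 7.42). No explanation was tested for these single values.

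For each comparison the 8 arrays can be split into groups of 4 in 35 ways, and in each comparison 1 split, the real one, gave as many probes. The real counts were 12204, 3397 and 11256 and the highest others 3, 0 and 4. The planned bound treated arrays as exchangeable, but most of these splits part arrays that were joined into 1 sample, which keeps their counts low. Whole samples can be split in only 3 ways per comparison and 15 ways over the 3 groups, so chance stays open for these counts and the next ones at the level of samples. For the 1836 opposed probes, 3 of 100 splits of the 12 arrays, the real one included, gave as many, the highest other with 7757. That split put the 4 young arrays in the place of the ad libitum ones, which enter both comparisons, and mixed the aged arrays. The difference between young and aged arrays then gives opposite changes by construction. A high count can thus come from any shared group that stands apart. The value with the slide series as a block was 594. For the 40 list results past the threshold, 6 of 100 splits, the real one included, gave as many. The highest other gave 42, and the median of the others was 23 lists past the threshold.

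The ad libitum arrays departed from both other groups. The slide series as the whole cause is argued against, since 4147 probes differed between the diets within the series that holds both. The day of scanning stays open for this departure, because 0 arrays of the other groups were scanned with the ad libitum arrays, and the scan cannot be told apart from free feeding at 24 months. That all but 1 pair of these 4 arrays stayed within the limit for repeat spots may also mean that they hold 1 sample, whose own state would then enter both comparisons. An effect of age and diet stays among the open explanations, as untested.

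The young arrays fell into 2 joined samples, arrays 1 and 2 and arrays 3 and 4, and 2549 probes differed between them by at least 2-fold, 569 higher and 1980 lower on arrays 1 and 2. Spp1, for example, was at 7.59 and 7.78 on arrays 1 and 2 and at 9.82 and 9.89 on arrays 3 and 4. Lower signal on arrays 1 and 2 stays open. Of the probes higher there 36 were above the median probe on both pairs, against at most 1 between arrays of a pair. The other 533 were not, and up to 593 such probes differed as much in 1 direction between arrays of a pair. Of the lower ones 23% were brighter than the median probe by the young arrays and 34% by the aged ones, and a true fall would lower probes too. The design gives no group within the young rats, so no biological explanation was tested.

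Markers of immune cells were higher in aged kidney, with a median log2 change of 1.45 (quartiles 0.76 and 2.08) for macrophage genes. Fewer tubule cells in the aged samples, which would raise markers of the other cell types alike, is argued against as the whole cause, since the higher of the upper quartiles of the endothelium and glomerulus lists was 0.54, below the lower quartile of the macrophage genes. This holds only if endothelial and glomerular cells were not lost along with tubule cells, which was not tested. The day of scanning or the slide series as the whole cause is argued against as well. Restricted arrays 1 and 2 share both with the young arrays, and between them the lower quartile of the macrophage genes was 0.92. Blood left in the tissue stays open: the median of the red blood cell list was -0.33, but its highest member, the haem synthesis gene Alas2, stood at 1.12, above the lower quartile of 0.76 of the macrophage genes with age, and haemoglobin genes had no probe of a single gene. The difference with age that the design names stays open as well, untested.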

How the results depend on the processing

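The fits over 5 samples, without pairs of young arrays and within a slide series were chosen only after the results were seen; the other alternatives were planned. All 4 counts of probes stayed within 1.5 times under 50 added before normalisation, cyclic loess, both filters on dim probes, no floor, kept quality flags and a variance trend. Under array median scaling 1162 probes were opposed, and 1119 with the value table, which also gave 2227 between the diets. A fit of only the 2 groups compared gave 7302 between the diets and 2888 opposed, and array weights, whose estimation stopped early with a warning, gave 8274 and 3513. With the slide series as a block 3887, 1479 and 594 probes passed for age, diet and opposition, and within slide series 2 restricted and young rats differed at 3417. With a minimum change of 1.5-fold, which by construction is stricter, 6222, 1332, 5717 and 636 passed for age, diet, restricted against young and opposition. Over 5 samples, by construction fewer, limma called 29, 0, 231 and 0, with 4331, 1207 and 5930 probes at an unadjusted p under 0.05 in the 3 comparisons, where 1270 are expected with no change. Without young arrays 1 and 2 there were 7797 diet and 3678 opposed probes, and without young arrays 3 and 4 7322 and 3760. Without a pair of young arrays, and in the fit of only the 2 groups compared, the diet changes are by construction unchanged. The higher diet counts there come from the estimate of spread, to which the difference between the young pairs adds in the planned fit. Except where the construction is named, the cause was not tested.

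Leaving out each array in turn, diet calls ranged from 2118 to 3882 and opposed probes from 1191 to 1973. The counts fell by more than 1.5 times without restricted array 2 (2118 and 1202), ad libitum array 2 (2158 and 1214) or ad libitum array 3 (2149 and 1191). The split covariance was -0.0791 on average, -0.0546 for probes above background on all 12 arrays and -0.0682 under array median scaling. The first component held 65.4% of the variance before normalisation and 55.1% after. Of 93 list tests 40 passed, 27 with an estimated correlation. Among them 8 lost their call under array median scaling, 7 with the value table, 4 with the slide series as a block and 3 over 5 samples, and of the values for named genes 43, 49, 55 and 351 did, in that order. Oxidative phosphorylation between the diets, which did not pass in the planned fit (median -0.03, adjusted p = 0.932, slightly up relative to other probes in camera), passed as lower under array median scaling (adjusted p = 0.00385) and with the value table (0.00271). Without young arrays 1 and 2, the proximal tubule, collecting duct, oxidative phosphorylation and cholesterol lists also passed as lower with age, and the loop of Henle, oxidative phosphorylation, cholesterol and insulin lists as lower between restricted and young rats. Between restricted and young rats, Sds turned to 0.31 without young arrays 1 and 2 and Aqp1 to 0.83 without young arrays 3 and 4, both then past the threshold. The cause was not tested.

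With the replicate number as a block 11406, 2641, 10553 and 1445 probes passed for age, diet, restricted against young and opposition, and the circadian lists of the last 2 comparisons no longer passed. Deviations of arrays with the same number correlated between -0.178 and 0.157, 3 of 12 pairs above 0.1, and 2 arrays matched their own number best in both other groups, so the numbers do not pair the samples. The scan as a block was not run, since it cannot be estimated for comparisons with the ad libitum group. Signal over background limits the results to the 75% of gene probes that could be tested, and arrays of the same sample limit the error that can be known.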

Other observations

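The following values were chosen for mention after they were seen, from the genes that the fixed rule names, and no hypothesis of their own was tested. Between the diets the members of the immune lists that passed moved in both directions, and most members did not pass. Of these lists only the interferon one passed with both the preset and the estimated correlation. Of 30 macrophage genes 6 fell and 3 rose, of 40 chemokines and cytokines 3 and 3, of 20 complement genes 3 and 0, of 8 B and plasma cell genes 2 and 0 and of 21 T and natural killer cell genes 4 and 0. In the MHC list 0 of 18 fell and 2 rose, and in the interferon list 0 of 24 and 9. Of single genes, S100a9, a neutrophil protein, rose by 2.16 (SE 0.19, n = 5 samples) and fell by 1.43 (SE 0.19). The limma adjusted p of that fall was 7.75e-07 in the fit over all arrays. Jchain rose by 2.87 (SE 0.24) and fell by 0.99 (SE 0.24), and Ccl5 rose by 2.81 (SE 0.25) and fell by 0.94 (SE 0.25). C1qb rose by 2.27 and fell by 0.52 (SE 0.22). Tff3 moved the other way, from -2.37 with age to 0.84 (SE 0.20) with restriction.

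Vnn1, Per1 and Sgk1 ended on the far side of the young level. Vnn1 rose by 1.22 (SE 0.25) with age, fell by 2.42 with restriction and lay at -1.21 (SE 0.20) against young rats. Per1 rose by 0.88 (SE 0.20), fell by 1.77 and lay at -0.88 (SE 0.16). Sgk1, a kinase of sodium transport induced by corticosteroids, rose by 0.77 (SE 0.22), fell by 1.39 (SE 0.22) with restriction and lay at -0.62 (SE 0.18) against young rats, though its age change did not pass under array median scaling (0.20, adjusted p = 0.0956). Fabp4 rose by 1.62 (SE 0.20) with age, fell by 0.97 and stayed above young rats by 0.65 (SE 0.16). Cidec, a lipid droplet protein, was lower in both aged groups, at -1.57 (SE 0.29) with free feeding and -1.75 (SE 0.23) with restriction.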
